A study of Mus musculus with 12 samples.

How the data were processed

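ac4C RIP-seq and total RNA sequencing were carried out on mouse peritoneal macrophages with IFN-γ for 0, 24 or 48 h, 2 samples for each of the 6 groups. Per the submitters' processing notes, BWA 0.7.12, MACS2 2.1.0 and the mouse genome build GRCm39 were used; the roles and settings of these tools are not given in the sources used here. BWA does not align reads across splice junctions, so fragments that span one may be missing or misplaced. The deposited tables hold 1 row for each summit and each gene it overlaps, with the authors' gene annotation. Fold enrichment is the authors' ratio of the signal at the summit over the background of the peak caller, and p and q are the authors' values as −log10, per the file headers. The smallest deposited −log10 p lies between 2.30 and 2.33 in the lists, so the authors' threshold was near p of 0.005, and 25.0% to 45.4% of the peaks of a list have a q of 1. The lists are per list of a time and not pooled over a time; which sample each comes from is not stated, so the number of a list pairs nothing. Which library was the control of a list is not given in the sources used here, and it is called input. The total RNA libraries were not analysed here.

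A peak was 1 region of chromosome, start and end, its strength that of its best summit. Starts and ends are printed as deposited; whether starts count from 0 or 1 is not stated, so a start can be off by 1 base. Covered length counts each base once. The centre of the peak, as the authors annotated it, gave its place (3′ UTR, 5′ UTR, last exon, other exon, intron, outside genes); the design had named the summit, for which the tables give no annotation, and coding exons are not separated from other exons. A region with several annotations took the first of that order, so that 3′ UTR had precedence. A gene had a peak when the centre lay in its body. Protein-coding genes were taken by symbol from a RefSeq table of another build (GRCm38.p6), used only for names and gene types; 94.4% of the 2103 gene symbols in the lists matched by symbol or synonym, and the mitochondrial genes were assigned from their names. Genes that did not match were not counted as protein-coding.

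Comparisons were fixed before the data were examined, except the shuffles, which were not part of that plan. Numbers per list were compared by two-sided exact permutation tests, whose smallest p is 0.33 for 2 lists against 2 and 0.067 for 2 against 4, and by an exact Jonckheere-Terpstra trend test over the 90 arrangements, whose smallest p is 0.022. Lists were compared by the Jaccard index in bases over 15 pairs, with an exact one-sided test over the 15 pairings. Regions of all lists were merged at an overlap of 1 base; a region or gene was lost or gained when it had a peak in both lists of one time and in neither of the other. A sustained loss was a peak in both 0 h lists and none of the 4 later, a sustained gain the reverse. For 28 gene lists, 6 of them markers of other cell types, Fisher's exact test (two-sided) compared members with other genes where 5 or more members could have changed, with Benjamini-Hochberg adjustment. The losses and gains at 24 h, at 48 h and at both were set against 1000 shuffles of each gene's lists, weighted by the number of genes of a list.

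Named genes followed a rule: protein-coding genes were ranked by the mean percentile of −log10 p of their strongest peak within the lists that hold it. Named were the 10 highest sustained losses, the 10 highest sustained gains (8 existed), the 8 highest in all 6 lists, the 5 highest lost and the 5 highest gained between 24 h and 48 h and at one later time only. Nat10 and Thumpd1 were always named, and from the interferon, MHC, inflammatory, alternative activation and resident lists the 4 highest of each class. Other genes, such as members of tested lists, are named where a count is 5 or fewer.

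The depth of the libraries is not given in the tables. The authors' fold and p at every summit were reproduced, within 0.005 of −log10 p, by a whole number k of pull-down fragments multiplied by 1 factor per list, with fold equal to (k times the factor, plus 1) over (input coverage plus 1) and p the upper tail of a Poisson distribution. The tolerance and the range of k were widened after some of the strongest summits had not been matched, and 100% of the summits then matched in each list. The factor, input over pull-down depth, was 0.437 and 0.468 at 0 h, 0.295 and 0.33 at 24 h, and 0.293 and 0.259 at 48 h. The lowest input coverage of a list, shared by 27 to 54 summits, was taken as its genome background and so as its relative input depth. The median summit held 45 to 51 pull-down fragments. For matched input coverage, fragments and input coverage of each summit were multiplied by the ratio to the shallowest list and p recomputed, and summits at p of 0.005 or less were kept; this can remove peaks and does not add the chance peaks of a shallower library.

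Alternatives were a q of 1e-05 or less, a fold of 4 or more, equal list length (611 peaks), 50% reciprocal overlap, assignment by exon or by any overlap, autosomes and X alone, 10000 random gene sets matched on peak strength, loss at 24 h or 48 h alone, and leaving out each list. A q of 0.05 or less, matched input coverage and gene list tests without each list were chosen after seeing the data. The planned base composition of peaks was not run, since it needs a genome of the same build. On simulated lists with 200 sustained losses among 1779 genes, 100% of the losses were called, which checks the code alone. Each was placed in both 0 h lists and no other, so the call was fixed in advance. With the lists of the remaining genes shuffled regardless of list length, 23 other genes were called. Of 25 simulated gene lists without a change none passed. The 1 simulated list with a change passed, but most of its genes were drawn from the losses, so it says little on smaller changes. In simulated summits with 3 known factors at least 99.9% of the fragment numbers were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.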

Results

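The study followed mouse peritoneal macrophages, phagocytes taken from the abdominal cavity, through 0, 24 and 48 h with interferon-γ (IFN-γ), the cytokine that drives classical macrophage activation. RNA carrying N4-acetylcytidine (ac4C), an acetylated form of cytidine that the enzyme NAT10 writes into RNA, was pulled down and sequenced (RIP-seq) beside total RNA. The 12 samples formed 6 groups of 2, 1 pull-down group and 1 total RNA group at each of the 3 times. No group without IFN-γ was taken at 24 h or 48 h, so IFN-γ cannot be told apart from the time elapsed. The results rest on 6 deposited peak lists, 2 per time, each giving the regions where the peak caller found the pull-down enriched over its background. The lists name their hour and not their sample, so they are called list 1 and list 2 of a time, without any order. Nothing in the labels says that the samples of a group came from separate animals or cultures, so the p-values measure the spread between these lists, which may be technical. Fold enrichment, p and q of each peak are the authors' values and serve to describe, rank or filter peaks within a list. Fold and p also gave the relative depth of the lists, by which the lists were matched below.

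At 0 h the lists held 1151 and 946 ac4C peaks over 825 and 702 protein-coding genes. At 24 h they held 725 and 646 peaks over 531 and 474 genes, and at 48 h 674 and 611 peaks over 519 and 463 genes. The mean number of peaks was 1049 ± 145 (SD, n = 2 lists) at 0 h, 685.5 ± 55.9 (SD, n = 2) at 24 h and 642.5 ± 44.5 (SD, n = 2) at 48 h, a log2 ratio to 0 h of -0.61 at 24 h and -0.71 at 48 h. Peaks with a q of 1 made up at most 26.2% of a 0 h list and 38.9% to 45.4% of a later one. At a q of 0.05 or less the means were 533, 258.5 and 250 at 0, 24 and 48 h. The log2 ratios to 0 h were then -1.04 and -1.09. At a q of 1e-05 or less the means were 248, 96 and 95.5, with log2 ratios of -1.37 and -1.38. At a fold of 4 or more the log2 ratios were -0.66 and -0.24. As deposited, both 0 h lists were longer than all 4 later lists, which gave the smallest p that 2 lists against 4 allow (two-sided exact permutation p = 0.067). Each time against 0 h alone could not go below p = 0.33 (exact, two-sided), and both comparisons stood at that value. The covered length was 341 ± 43.9 kb at 0 h, 214 ± 22.9 kb at 24 h and 187 ± 0.876 kb at 48 h (SD, n = 2 lists each). It was the only measure with a trend past 0.05 (exact two-sided Jonckheere-Terpstra test, p = 0.022, the smallest it can give), and 4 other settings ended that call: a fold of 4 or more, matched input coverage, and a q of 1e-05 or of 0.05 or less. The same trend test gave an exact p of 0.067 for the number of peaks and for the number of genes.

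**Figure D1:**
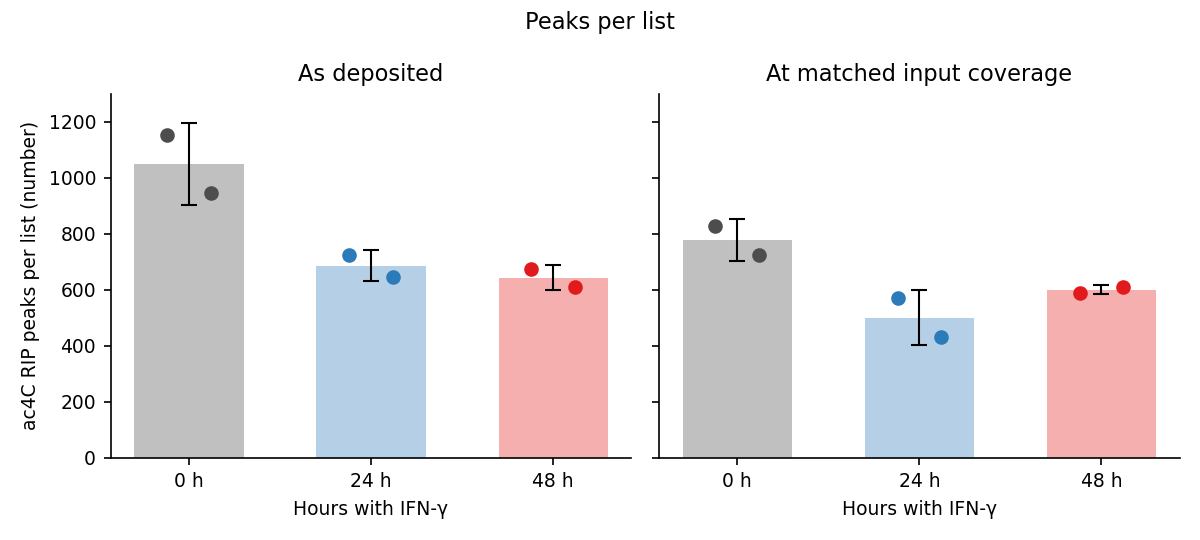
Number of ac4C RIP peaks per list against hours with IFN-γ, as deposited (left) and after every list was brought to the input coverage of the shallowest one (right); points are the 2 lists of a time, bars their mean and whiskers the SD. The 0 h lists sit at 946 and 1151 as deposited and at 723 and 829 when matched, above all later lists in both panels.

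The depth behind the lists differed between times. Which library served as the control of a list is not given in the sources used here; the control coverage is called input coverage below. The fragments under each summit, recovered from the authors' fold enrichment and p, put the input coverage of the 0 h lists at 100% and 91.4% of the deepest list, that of the 24 h lists at 73.7% and 80.8%, and that of the 48 h lists at 57.2% and 44.5%. The pull-down coverage was highest at 24 h, at 100% and 98.0% of the deepest list, against 91.5% and 78.0% at 0 h and 78.0% and 68.6% at 48 h. At matched input coverage the lists held 829 and 723 peaks at 0 h, 570 and 431 at 24 h, and 589 and 611 at 48 h. The log2 ratio to 0 h was then -0.63 at 24 h and -0.37 at 48 h, and the 48 h lists were longer on average than the 24 h lists, by 0.26 on the log2 scale against -0.09 as deposited (two-sided exact permutation p = 0.33 and p = 0.667, n = 2 against 2). Matching can only remove peaks, and the shallowest list, 48 h list 2, kept all of its 611 peaks. The order of 48 h and 24 h after matching is therefore tilted toward 48 h.

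Among the highest-ranked genes whose peaks were lost after 0 h were a chaperone, splicing factors and surface receptors of the macrophage. Of the 372 protein-coding genes with a peak in both 0 h lists, 101 had none in any of the 4 later lists, which is called a sustained loss below. Genes were ranked by the mean percentile of −log10 p of their strongest peak within a list, and the first was Hsp90ab1 (ENSMUSG00000023944), a cytosolic chaperone, with a peak in exon 6 at chromosome 17, 45881268 to 45881577 (GRCm39), at a fold enrichment of 2.37 and a −log10 q of 21.6. Itgam (ENSMUSG00000030786), the CD11b chain of the complement receptor CR3, had its peak in the 3′ UTR at chromosome 7, 127716623 to 127717066. Il10rb (ENSMUSG00000022969), a chain of the IL-10 receptor, had its peak in the 3′ UTR at chromosome 16, 91222454 to 91222710, at a fold enrichment of 4.13. Tfrc (ENSMUSG00000022797), the transferrin receptor that takes up iron, had its peak in the 3′ UTR at chromosome 16, 32449399 to 32449735. The splicing factors Sfpq and Srsf3 had theirs in the 3′ UTR and the last exon, at folds of 5.43 and 3.36. The small GTPase gene Rhob had a 3′ UTR peak at a fold of 3.14 and the tubulin gene Tuba1c a last-exon peak at 3.74. The 10 highest-ranked losses also held Hsd17b4 and Tmem132d, whose peaks lay in introns 2 and 4; with genes assigned by exon neither had a peak in any list, and 8 of the 10 kept their pattern. The Hsd17b4 peak also lay on Cd63-ps, a pseudogene copy of the tetraspanin gene Cd63, so its gene is uncertain. In 9 of the 10 genes a single merged region had the same pattern over the lists as the gene, Sfpq being the exception.

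The sustained losses outnumbered what other choices of lists gave, by a margin that shrank at equal list length and at a fold of 4 or more. Of the 15 ways to choose 2 of the 6 lists, the 0 h lists had the most genes of their own, 101. The next highest choice had 37. The 0 h lists also held the most genes, 825 and 702 against 463 to 531 later, which favours that choice whatever the time. The lost genes numbered 154 at 24 h and 141 at 48 h. The other splits of the same 4 lists gave 25 to 53 genes at 24 h and 27 to 67 genes at 48 h. Each side of those splits mixes a longer 0 h list with a shorter later one, so they do not show what list length alone gives. The comparisons of 24 h and of 48 h with 0 h share the 0 h lists. When each gene's peaks were shuffled over the lists in proportion to list length, 90.4 genes on average (64 to 120 over 1000 shuffles) were lost at 24 h. At 48 h the shuffles gave 91.5 genes (64 to 120). In the same shuffles 49.7 genes (30 to 71) were lost at both times, and independent losses would share 58.4 genes. The shuffles hold the shared 0 h lists but not the excess of losses at each time. The value for independent losses holds that excess but takes all 372 genes as equally likely to be lost. The lost genes had weaker 0 h peaks, with a median percentile of 50.6 against 71.1 for the others. Part of the excess over 58.4 may therefore come from differences between genes. At equal list length, the 611 peaks with the smallest p of each list, 44 genes had a sustained loss and the highest other choice gave 31. At fold enrichment of 4 or more these numbers were 19 and 16, at matched input coverage 74 and 28, and at a q of 1e-05 or less 44 and 5. With genes assigned by exon they were 97 and 35. At that fold, at matched input coverage and at that q both 0 h lists still held more peaks than every later list.

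**Figure D2:**
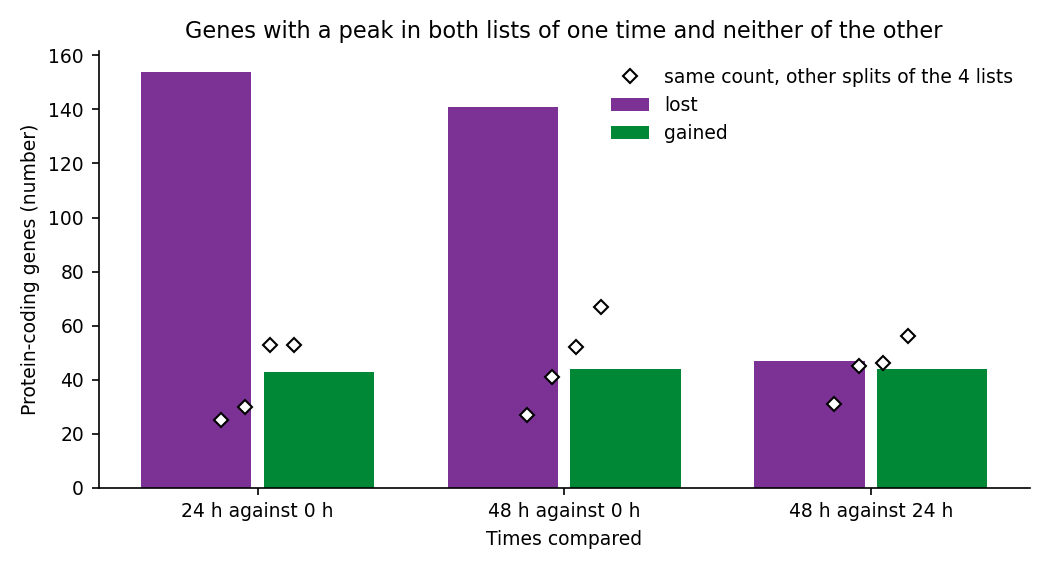
Number of protein-coding genes with a peak in both lists of one time and in neither list of the other, for each pair of times (bars, lost in purple and gained in green); diamonds are the same count for the other splits of the 4 lists. The lost genes stand at 154 and 141 against 0 h, above the diamonds, and the gained genes at 43 and 44 lie among them.

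Gained peaks were fewer, and their number was within that of other splits of the lists. The genes with a peak in both lists of a later time and in neither 0 h list numbered 43 at 24 h and 44 at 48 h. Shuffles weighted by list length gave 33.5 on average (18 to 52) at 24 h and 32.3 (13 to 51) at 48 h. They too gave fewer gains than losses, so list length alone yields that order. A peak in all 4 later lists and in neither 0 h list was found for 8 genes, Kmt5a, Inhba, Rbpj, Zmiz1, Pds5a, Ctss, Yme1l1 and Zc3h11a; the other choices of 4 lists gave 0 to 15 genes. For a sustained gain the shuffles gave 2.68 genes on average (0 to 9). At equal list length 11 genes had a sustained gain, above the 2 to 9 of the other choices. Kmt5a (ENSMUSG00000049327), the histone H4 lysine methyltransferase, ranked first, with a peak in the 3′ UTR at chromosome 5, 124598878 to 124599149, at a fold of 4.15 and a −log10 q of 17.1. Inhba (ENSMUSG00000041324), the activin A subunit, had its strongest peak in the 3′ UTR at chromosome 13, 16201724 to 16201942, at a fold of 3.38. Ctss (ENSMUSG00000038642), the protease that trims the MHC class II invariant chain, had its strongest peak in the last exon at chromosome 3, 95463467 to 95463679, at a fold of 4.24. Rbpj, the transcription factor of Notch signalling, had a 3′ UTR peak at a fold of 2.89, and Pds5a, a regulator of cohesin, a peak in exon 32 at a fold of 6.6. The Zc3h11a peak lay in intron 2 and its q was 1. Only 3 of the 8 genes, Kmt5a, Inhba and Yme1l1, had 1 merged region with a peak in all 4 later lists, and in the other 5 no single region had the pattern of the gene. At matched input coverage 3 genes had a sustained gain, Kmt5a, Rbpj and Pds5a.

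Kpna4, Arf3, Rab7, Cfl1 and Actb were among the genes with a peak at every time. A peak in all 6 lists was found for 59 genes, with a median percentile of 83.0 for their strongest peaks at 0 h. Kpna4, an importin, held the highest-ranked of them, in intron 12 at chromosome 3, 68992451 to 68992756, at a fold of 8.2; the same peak lay on Gm22009, a guide RNA gene, and with genes assigned by exon Kpna4 had a peak in only 2 lists. Arf3 and Rab7, small GTPases, had 3′ UTR peaks at folds of 4.96 and 2.93. The actin regulator Cfl1 and Actb itself had 3′ UTR peaks at folds of 2.42 and 1.83; at a q of 1e-05 or less Actb was missing from 1 of the 24 h lists. Ifrd1 and Gsk3b had 3′ UTR peaks at folds of 8.04 and 6.06, and Ncl, the nucleolar protein nucleolin, had a peak in exon 4 at a fold of 4.75.

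Some high-ranked 0 h peaks were missing at one later time only. These were Ptma (prothymosin α), Npm1 (the nucleolar protein nucleophosmin), Adcy9 and a 3′ UTR peak shared by the overlapping genes Pcbp2 and Map3k12. Each was found in both 0 h lists, in neither 24 h list and in 48 h list 2. None had a peak in 48 h list 1, so their presence at 48 h rests on the same 1 list. The Ptma peak, in the 3′ UTR, had a fold of 5.57 in 0 h list 2, and the Npm1 peak, in the 3′ UTR, 4.95 in 48 h list 2. The Adcy9 peak lay in intron 4 and also on the pseudogene Gm6142. Gained at 48 h against 0 h and not at 24 h were Rpl41, a ribosomal protein gene, Selenow, a selenoprotein gene, and Cd33, a sialic acid-binding receptor of myeloid cells, at folds of 3.51, 5.06 and 4.73; Selenow also had a peak in 1 of the 24 h lists. Gained at 24 h and not at 48 h were Nfkbiz, a nuclear regulator of NF-κB, and the interferon-induced gene Slfn5, at folds of 4.45 and 5.71; both also had a peak in 1 of the 48 h lists.

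**Figure D3:**
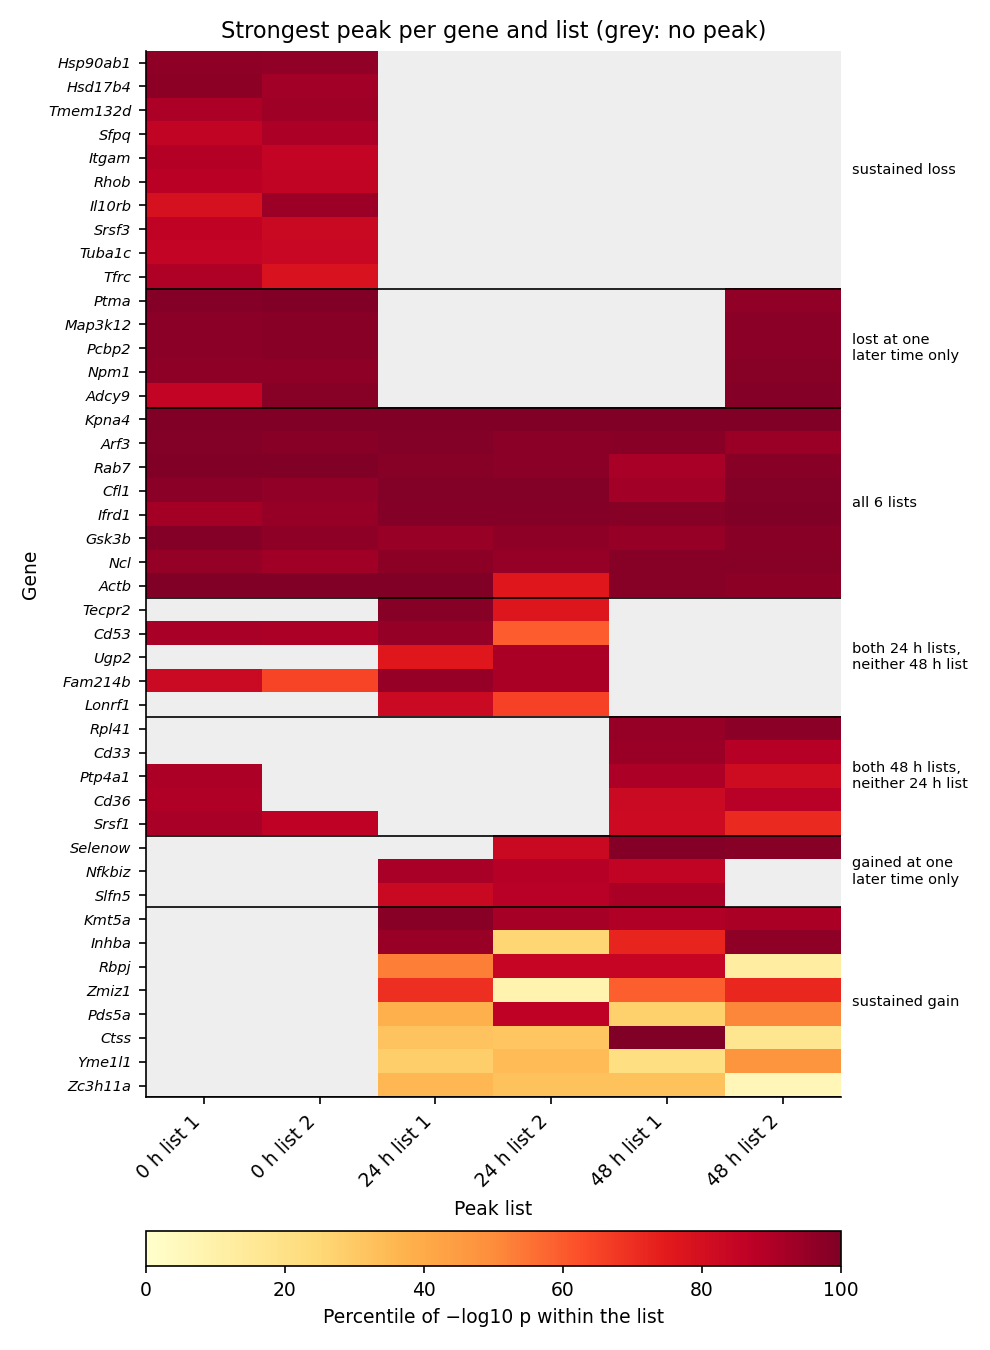
Genes named by the fixed rule (rows) in the 6 peak lists (columns), coloured by the percentile of the gene's strongest peak by −log10 p within that list and grey where the list has no peak in the gene; percentiles come from lists of different lengths and show no change between columns. Rpl41 and Cd33 belong to the genes gained at 48 h only as well as to those with peaks in both 48 h lists and neither 24 h list.

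Between 24 h and 48 h similar numbers of genes were lost and gained in the lists as deposited, and the balance moved with the setting: 7 lost and 19 gained at a fold of 4 or more, 23 and 44 at matched input coverage, 8 and 4 at a q of 1e-05 or less, and 16 and 20 at a q of 0.05 or less. In the deposited lists a peak in both 24 h lists and neither 48 h list was found for 47 genes, and the reverse for 44, within the 31 to 56 genes of the other splits of these 4 lists. The highest-ranked of the first kind were Tecpr2 (in an intron, on the pseudogene Rps19-ps6), Cd53, a leukocyte tetraspanin, Ugp2, Fam214b and Lonrf1. The highest-ranked of the second kind were Rpl41, Cd33, the phosphatase gene Ptp4a1, the scavenger receptor gene Cd36 and the splicing factor gene Srsf1. At a q of 1e-05 or less, 0 of the 5 named genes of the first kind had the same lists. Of the 5 of the second kind 2 did, Rpl41 and Cd33. Over merged regions the same counts were 58 and 52, against 205 lost and 43 gained at 24 h and 193 lost and 54 gained at 48 h relative to 0 h. The other splits gave 34 to 73 regions over the 3 comparisons.

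The 3′ UTR was the most frequent place of a peak in each of the 6 lists, when last exons and other exons are counted apart. The centre of the peak lay in a 3′ UTR for 52.9% ± 3.68 (SD, n = 2 lists) of peaks at 0 h, 40.5% ± 3.82 (SD, n = 2) at 24 h and 52.9% ± 9.28 (SD, n = 2) at 48 h. Exons outside the UTRs, last and other exons together, held 30.7% ± 3.64, 41.3% ± 4.19 and 32.0% ± 7.25 of peaks at 0, 24 and 48 h (SD, n = 2 lists each). At 24 h both lists had a smaller 3′ UTR share than both 0 h lists, by 12.4 percentage points on average (-12.4 for 24 h minus 0 h), and a larger share in exons outside the UTRs, by 10.6 points; the exact two-sided permutation p of each was 0.33, the smallest that 2 lists against 2 allow. At 48 h the lists stood apart, at 46.3% and 59.4% in 3′ UTRs. Introns held 4.71%, 6.3% and 4.53% of peaks on average, and 8.76%, 8.43% and 7.73% lay outside genes.

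Of the 56 interferon-induced effectors examined, 7 had a peak in any list, beside 12 of 79 ribosomal protein genes, 9 of 56 genes of oxidative phosphorylation and 18 of 38 lysosomal genes, with no test between these lists. The 7 were Slfn5 in 3 later lists, Cd274 (PD-L1) in both 0 h lists, 1 at 24 h and 1 at 48 h, and Acod1, Ifi209, Gbp3, Ifi207 and Bst2 in 1 later list each. Of the 22 genes of IFN-γ signalling 4 had a peak in any list: Ifngr2, a chain of the IFN-γ receptor, in 5 lists, Jak2 in 3, Irf1 and Irf5 in 1 each. Among the 22 genes of MHC class I presentation the peptide-loading factor Tapbp had a sustained loss, and the chaperones Canx and Calr had peaks in 2 lists and 1 list. Among the 15 genes of MHC class II presentation Ctss had a sustained gain, and Ctsl, Cd74 and Ifi30 had a peak in 1 list each. Of 39 pro-inflammatory genes 10 had a peak in any list, among them Cxcl2 in 4 lists, Nfkbia in 5, Nfkbiz in 3 and Tnf in 2. Of 39 genes of alternative activation 11 had a peak in any list: among them, Hmox1 had a peak in all 6 lists, Sirpa and Spp1 in 5, Cd36 in 3 and Mmp12 in 1, while Stat6 was lost at 48 h only and Vegfa, which also had a peak in 1 of the 24 h lists, gained at 48 h only. Of 38 genes listed for resident peritoneal macrophages, Cebpb had a peak in 5 lists and Itgam a sustained loss. Lyz2, Serpinb2 and Wt1 had a peak in 1 list each. Wt1 is a gene that mesothelial cells express, so its peak, in 48 h list 2, need not come from macrophages. Neither Nat10 nor Thumpd1, the enzyme and its adaptor, had a peak in any list. A missing peak is not a low transcript level, since the lists give no level below their threshold.

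No gene list passed its test, and 1 list, the translation factors for gain, had an unadjusted p under 0.05. Only the 2 lists with 5 or more members among the 372 genes could be tested for loss: 1 of 8 translation factors (Gspt1) and 2 of 7 cytoskeleton and adhesion genes (Actn4 and Cd44) had a sustained loss, with an adjusted p of 1 for both (Fisher's exact test, two-sided, Benjamini-Hochberg over 2 lists). For gain, 5 lists could be tested among 624 genes with no 0 h peak, of which 79 were gained at 24 h or 48 h. Of 5 translation factors 3 were gained, Eif1ax and Eif5 at 48 h and Etf1 at 24 h (Fisher's exact p = 0.016, adjusted p = 0.081 over 5 lists); Eif1ax also had a peak in 1 of the 24 h lists. The difference in gained share, 47.7 percentage points, ranged from 8.89 to 53.2 without 1 list, for the 5 of 6 lists whose removal left enough members to test. The interferon-induced effectors and the lysosomal genes each had 1 of 6 members gained, and the ribosomal protein and pro-inflammatory lists 1 of 5, with an adjusted p of 0.558 for each (Fisher's exact test). Genes are not independent replicates in these tests. Of the 6 lists of markers of B cells, T and NK cells, neutrophils and eosinophils, mast cells, mesothelial cells and fibroblasts, and dendritic cells and monocytes, none had a member with a peak in any of the 6 peak lists. Wt1, which had a peak, was not a member of the mesothelial list.

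Peak lists of the same time resembled each other most at 0 h. The 0 h lists shared 24.9% of the bases either covered (Jaccard index), the 24 h lists 16.5% and the 48 h lists 15.7%, and the 12 pairs of different times 13.0% to 17.5%. The same-time mean of 19.0% exceeded the other mean of 15.1% by 3.89 percentage points, the largest difference of all 15 ways to pair the lists (exact one-sided permutation p = 0.067, the smallest possible). It was no longer the largest at 50% reciprocal overlap or at a q of 1e-05 or less (exact one-sided permutation p = 0.133 for each). At that q the 24 h lists shared 24.1% of bases and the 48 h lists 27.2%, and 1 pair of different times 32.6%. This value rested on the 0 h pair: without 0 h list 1 or 0 h list 2 the difference in the index was 0.00966 or 0.00751, against 0.039 with all 6 lists. Of the 2808 merged regions, 63.2% had a peak in 1 list and 1.96% in all 6.

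**Figure D4:**
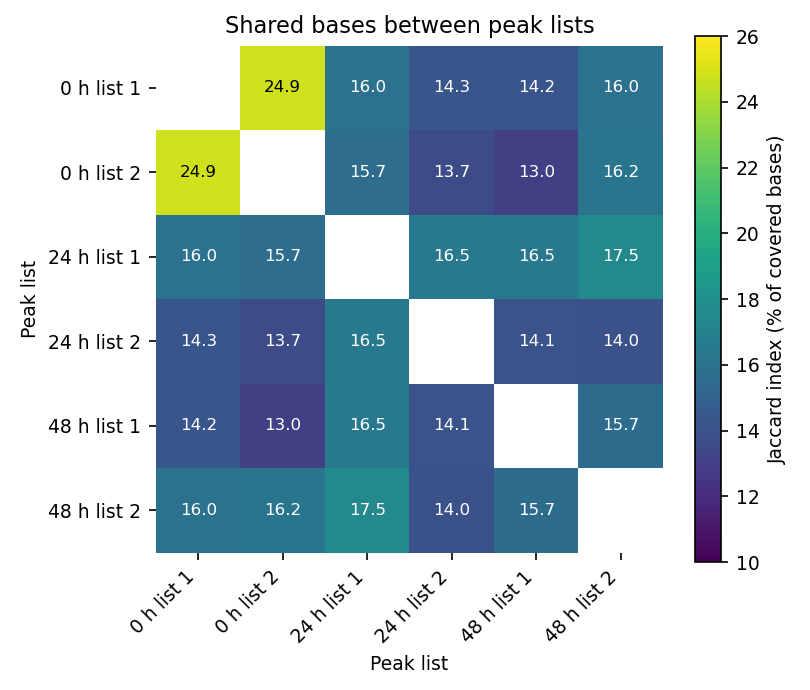
Jaccard index, in percent of the bases covered by either list, for each pair of the 6 peak lists (both axes). The pair of 0 h lists stands at 24.9, and every other pair lies between 13.0 and 17.5.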

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

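Matched input coverage, the q of 0.05 and the gene list tests without each list were chosen after seeing the data; the cause of a difference was not tested unless stated. Lower peak numbers and covered lengths at 24 h and at 48 h than at 0 h kept their direction under every setting that gave a value (at equal length, covered length alone), and 0 gene lists passed under any. No paired analysis was possible because the lists carry the hour and not the sample. Base composition was not run, and equal length gives no peak number. With 2 lists per time no pairwise p can pass 0.05, so an unchanged side of the threshold says nothing about stability there.

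The covered-length trend (-1) lost its call at a fold of 4 (-0.33, exact permutation p = 0.578), matched input (-0.50, p = 0.33), q of 1e-05 (-0.83, p = 0.067) and q of 0.05 (-0.83, p = 0.067), and without any 1 list (-1 each time), where 5 lists are too few for it to pass. For 48 h against 24 h, log2 peak number turned to 0.42 at a fold of 4 and 0.26 at matched input, covered length to 0.39 and 0.13, and genes to 0.415 and 0.29, with 0.0038 at a q of 0.05. Equal length fixes the number of peaks, and log2 genes turned to 0.00798 (24 h against 0 h), 0.049 (48 h against 0 h), 0.041 (48 h against 24 h) and 0.029 (both later times), trend 0.75. The 3′ UTR share at 48 h minus 0 h turned to 2.76 points at a fold of 4 and 0.397 at a q of 0.05.

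Stricter thresholds leave fewer peaks to count. Regions lost and gained were 29 and 4 (24 h against 0 h), 27 and 18 (48 h against 0 h), 3 and 17 (48 h against 24 h) at a fold of 4; 75 and 9, 75 and 7, 11 and 6 at a q of 1e-05; 121 and 15, 117 and 22, 21 and 21 at a q of 0.05. Genes lost and gained were 21 and 7, 22 and 20, 7 and 19, sustained 19 and 0, at a fold of 4; 57 and 7, 59 and 6, 8 and 4, sustained 44 and 1, at a q of 1e-05; 101 and 11 (24 h), 18 gained at 48 h, 16 and 20 (48 h against 24 h), 2 sustained gains at a q of 0.05. At equal length 113 regions were lost and 65 gained at 24 h and 95 lost at 48 h, and 79, 64 and 44 genes lost at 24 h, at 48 h and at both. At matched input 128 regions were lost at 48 h, 29 regions and 23 genes from 24 h to 48 h, and 3 genes had a sustained gain.

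Leaving out 1 list leaves a time with 1 list, where both lists becomes 1 and counts grow by construction. Regions lost and gained then ranged 205 to 767 and 43 to 389 (24 h against 0 h), 193 to 751 and 54 to 372 (48 h against 0 h), 58 to 419 and 52 to 395 (48 h against 24 h); genes 154 to 476 and 43 to 234, 141 to 440 and 44 to 225, 47 to 246 and 44 to 247, sustained 113 to 346 and 9 to 21. Log2 genes at 48 h against 24 h ranged -0.12 to 0.051, the 3′ UTR share at 48 h minus 0 h -6.63 to 6.49 points and the share in exons outside the UTRs -3.88 to 6.37. The difference of the cytoskeleton list in lost share (1.45 points) turned to -9.59 at matched input, -39.5 at a q of 0.05, -20.1 at equal length, -13.1 and -9.51 for loss at 24 h and 48 h alone, and -7.59 to -1.84 without 1 list. Gains of the translation factor, interferon, pro-inflammatory, ribosomal and lysosomal lists ranged 8.89 to 53.2, -7.39 to 12.9, -7.39 to 33.1, -11.3 to 2.69 and -18.5 to 13.3 points without 1 list, and the lysosomal one was -0.077 at equal length.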

Other observations

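The tests of depth and of other choices of lists were chosen after the result was seen; the examples from the gene lists, the gene ontology terms and the non-coding genes were also chosen after seeing the data; the tests of peak strength were set before. Among the sustained losses outside the fixed order of strength were genes of several lists, chosen here after their values were seen: the DNA methyltransferase gene Dnmt1 and the DNA demethylase gene Tet3, the 2 chromatin regulators of the list with a peak in both 0 h lists; the RNA helicase gene Ddx21; the ribosomal protein gene Rplp1; the complex II gene Sdhd; and the disulfide isomerase gene Pdia6. In a post hoc test of the authors' gene ontology terms with 8 or more members, 0 of 205 terms passed an adjusted p of 0.05 (Fisher's exact test, Benjamini-Hochberg) among the 372 genes that could be lost, with 3 at an unadjusted p under 0.05, and 0 of 241 among the 624 that could be gained, with 8.

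Several non-coding RNAs carried peaks at every time. Malat1 had 5 to 6 peaks in each of the 6 lists, Neat1 had 1 to 3 in 5 lists and Norad 1 to 2 in 5 lists. The mitochondrial gene mt-Nd5 had a peak in all 6 lists. Pseudogenes held 4.08% to 6.5% of the peaks of a list. Over the 6 lists, 285 peaks lay in an intron of a protein-coding gene and in no exon of one. Of these, 61 lay on an exon of a pseudogene or a small RNA; among the 49 with a q of 1e-05 or less it was 27, of which 21 lay on a pseudogene.

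The first pattern was the smaller number of peaks at 24 h and 48 h than at 0 h. At matched input coverage the shorter 0 h list still had 153 peaks more than the longer 24 h list. Against the longer 48 h list it had 112 more. Uniform scaling to the shallowest input thus left a gap at both times. Shallower input coverage may account for part of the difference at 48 h. Matching left the factor of input over pull-down depth unequal, at 0.437 and 0.468 at 0 h against 0.259 to 0.33 later. It also redrew no fragments, so it cannot exclude shallower input coverage as the whole cause. Fewer ac4C RIP fragments do not account for 24 h, where 2 of the lists had more pull-down coverage than both 0 h lists. As deposited, that coverage was 78.0% and 68.6% of the deepest list at 48 h, against 91.5% and 78.0% at 0 h. After matching, 2 of the 0 h lists had less pull-down coverage than both 48 h lists, and still more peaks. Matching scaled pull-down and input by the same ratio and redrew no fragments, so it cannot decide whether fewer fragments play a part at 48 h. A weaker pull-down, a change in which transcripts the cells hold and a change in acetylation with IFN-γ remain open and were not tested here. Without a later group that lacked IFN-γ, an effect of IFN-γ cannot be told apart from one of the time elapsed.

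The second pattern was the low overlap between lists of the same time. Of the peaks with a q of 1e-05 or less, 71.2% (0 h), 58.3% (24 h) and 61.8% (48 h) were found again in the other list of that time, against 20.9%, 17.9% and 17.9% of the peaks with a q of 1. The smallest difference, 40.5 percentage points, is in line with many peaks near the lenient threshold being called by chance. No biological explanation was tested, and weak true peaks missed in 1 list would give the same picture.

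The third pattern was the sustained loss of peaks in 101 genes. Their peaks were weaker at 0 h, with a median percentile of 50.6 against 71.1 for the other 271 genes with a peak in both 0 h lists, a difference of 20.5 points (two-sided permutation p = 1e-05, the smallest that 100000 resamples give). Genes of the same 2 lists are not independent replicates, so this p does not measure the spread between lists. Weaker peaks would drop below the threshold first under other causes as well. The difference fits weak 0 h peaks as a cause of part of the loss. It does not show how much: the median of the lost genes lay in the middle of the lists, and 23.8% of them lay at or above the median of the others. The excess over the highest other choice of 2 lists depended on the setting, with 44 against 5 genes at a q of 1e-05 or less, where the 0 h lists held 271 and 225 peaks and the later ones 90 to 101, 44 against 31 at equal list length and 19 against 16 at a fold of 4 or more. Of the 15 choices of 2 lists, 1 had as many genes of its own, the 0 h lists themselves, with 37 for the highest other. The 0 h lists were also the longest, and 15 choices are too few for a share under 0.05. An effect of IFN-γ on these transcripts remains an open explanation, untested against their RNA level. The design cannot separate it from an effect of the time elapsed.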
